A study of Homo sapiens with 33 samples.

How the data were processed

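Pools of synthetic oligonucleotides were transfected into HEK293T cells, a human embryonic kidney line, and the cells were harvested 48 hours later and fixed with 0.1% formaldehyde for 10 minutes before immunoprecipitation. The labels name 5 pools, PUM2, MS2, hTR, CTCF and WRAP53, each read out by single-end amplicon sequencing of cDNA from the immunoprecipitate and from Input. The files hold the counts that the authors deposited, as 1 table per pool, with 1 line per tile and barcode and 1 column per library. Per the labels and the file headers these are raw read counts: all values were whole numbers and the column totals differed. The program that assigned reads to tiles and barcodes and its settings are not given in the sources used here, nor are molecular identifiers. PCR reads without such identifiers are not independent molecules, so floors and counting intervals cover counting error only.

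The 33 libraries fell into 11 groups of 3. Columns were matched to samples by name, and 0 columns of per-sample values were left unmatched. The PUM2 columns carry the letters A, B and C where the labels carry numbers, so those columns were placed in their group without a replicate number and, in the main fit, were not paired. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. The 33 library pairs within groups were compared by a chi-square test of their tile counts. The statistic per degree of freedom ran from 38.7 to 4620, so none of these libraries was a second copy of another in its group.

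Counts were summed over the barcodes of each tile, of which each pool holds a fixed number: 22 in the PUM2 pool, 50 in the MS2 pool, 25 in the hTR pool, 24 in the CTCF pool and 35 in the WRAP53 pool. Tile names give a source RNA or a class and a number. Sequences, positions in the source RNA and the meaning of the WRAP53-pool classes (ctrl, wt, single, stem) and of the 4x in the MS2-pool names were not used here. All 32 source RNA symbols of the PUM2 and CTCF pools matched the reference gene table. No genome was used, and no genomic position is given. The result for 1 source RNA of the PUM2 pool is not reported by itself here.

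Each pool was analysed by itself in R 4.3.3. Tiles were filtered with filterByExpr, scaled with TMM and tested with the quasi-likelihood F test of edgeR 4.0.16 (robust estimation). Benjamini-Hochberg adjusted p values under 0.05 were counted as calls. The 9 MS2 libraries were fitted together. Standard errors are the absolute log2 fold change divided by the square root of F. Log2 CPM (counts scaled to library size times the TMM factor) used a prior count of 2. Where a tile had 0 counts in all libraries of 1 group, its fold is given as a bound against 3 counts over that group. For barcode counts within a tile, barcodes with at least 30 reads over both groups were used. Source RNAs and name classes with at least 5 tested tiles were compared with the rest of their pool by camera (limma 3.58.1) with a preset correlation of 0.01 and again with an estimated correlation. The CTCF pool was also tested for a list of 8 RNAs reported earlier to associate with CTCF or with X inactivation. In the WRAP53 pool the log2 CPM of each single and stem tile minus that of wt_1 in the same library was compared between fractions with limma (trend and robust estimation), with wt_1 read as the unaltered tile from its name alone. Calls shared by FLAG and HA were set against 100 simulations of 9 libraries drawn from the Input means, so that the error of the shared Input was included, though not deviations shared by FLAG and HA.

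Named tiles followed a rule: the 10 highest and 5 lowest calls of a comparison whose libraries did not overlap between groups, the 2 highest and the 1 lowest tile of each class, the 3 highest and 2 lowest windows, up to 5 altered tiles in each direction, and the 3 smallest p values where nothing passed. The tests, groups, this rule and the alternative settings not marked otherwise below were fixed before the data were examined. The planned profile by position was replaced, after the data were seen, by means over 5 consecutive tile numbers of 1 source RNA, because names give no positions. The SD beside a window is that of its mean log2 CPM over the 3 immunoprecipitate libraries, each against the mean of Input, so it leaves out the spread between Input libraries. The 4 segments of the hTR pool (least squares on replicate 1, at least 20 tiles each) were also chosen after the data were seen.

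The alternatives were RLE size factors, library size only, no filter, a mean count of at least 50, the Wald test of DESeq2 1.42.0, the replicate number as a block, a log2 fold change of at least 1, each library left out in turn, 1 test per barcode, prior counts of 0.5 and 10, and an estimated correlation for classes. Fits without each tile's barcode of most reads, without the 8 tiles of most reads, without ctrl_1 without both fractions of replicate 1 and with the PUM2 column letter as a block were added after the data were seen. Whether replicate numbers pair the fractions was checked by correlating, across tiles, the deviations of same-numbered libraries from their group means, with 0.1 as the least correlation that counted. By this bound they paired in the hTR pool (0.90, 0.78 and 0.69), in the CTCF pool (0.70, 0.68 and 0.29) and between FLAG and HA (0.65, 0.14 and 0.15). Blocked values are therefore given beside those results where they differ by more than 1.5 times. The bound does not show that a number pairs only with itself. Replicate 3 correlated more with another number in the CTCF pool (0.57) and between FLAG and HA (0.59). For hTR replicates 2 and 3 the highest correlation with another number was 0.75 and 0.66, close to their own.

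The functions were tested on simulated data with the real depths and spread. Simulated libraries were drawn independently, so the deviations that same-numbered libraries share in the hTR and CTCF pools were left out. Of 50 tiles changed 2-fold per pool, the fit found 28 in the PUM2 pool, 18 in the hTR pool and 31 in the CTCF pool, and of 50 changed 1.5-fold it found 9, 6 and 11. The smaller pools had few such tiles: in the MS2 pool 5 of 5 changed 2-fold and 0 of 5 changed 1.5-fold were found, and in the WRAP53 pool 3 of 3 of each. Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for tables, permutation tests and plots. Scaling to negative controls was not run, because no pool names 10 of them, and the CTCF and WRAP53 pools were not compared tile by tile, because they share 0 tile names.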

Results

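Transcribed oligonucleotide pools were used to ask which stretches of an RNA are recovered with a protein from living cells. For each pool the scaled read count of every tile in the immunoprecipitate was compared with that in Input. Cells that received the PUM2 pool carried no added protein and were precipitated with an antibody against PUM2, a Pumilio-family RNA-binding protein. The MS2 pool was combined with FLAG-HA-tagged MCP, the MS2 phage coat protein, and precipitated through FLAG or through HA. The hTR pool was combined with FLAG-tagged hTERT, the catalytic subunit of telomerase, and the CTCF and WRAP53 pools with FLAG-GFP-tagged CTCF, a zinc-finger chromatin protein. Each of the 11 groups held 3 libraries.

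The 33 libraries held between 1216203 and 58020403 reads. PUM2 Input libraries held 29433144 to 35092298 reads and their immunoprecipitates 15986799 to 17727926. The ranges were 4104695 to 4880714 for MS2 Input, 4530657 to 5970277 for FLAG and 5513258 to 6843839 for HA. In the hTR pool Input held 8209243 to 8339343 and the immunoprecipitate 7108444 to 11780535 reads. In the CTCF pool these were 35234255 to 51341630 and 44570966 to 58020403, and in the WRAP53 pool 1305043 to 1510200 and 1216203 to 1322546. Of the PUM2-pool barcodes, 46.8% to 51.5% had no read in an immunoprecipitate library, against 9.16% to 9.40% in Input. A single tile, ctrl_1, took 24.4% to 31.5% of the WRAP53 Input reads.

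The anti-PUM2 immunoprecipitate was enriched for tiles of NORAD, a noncoding RNA with many Pumilio binding sites, and for tiles of most of the 22 mRNAs in the pool. The NORAD:34 tile was 51.2-fold higher than in Input (log2 fold change 5.68 ± 0.17, SE, n = 3 against 3), at 3140 ± 554 CPM against 61.3 ± 3.97 CPM (SD), with all 22 of its barcodes higher. MARCHF6:41 was 57.4-fold higher and RBM27:68 was 78.5-fold higher. The largest log2 fold changes belonged to tiles that were scarce in Input: EIF1AD:37 (9.40 ± 1.01) and EIF1AD:36 (8.33 ± 0.65) had 39 and 112 Input reads over 3 libraries. RBM27:69 (7.95 ± 0.50), VAPA:87 (7.18 ± 0.65), LNPEP:94 (6.70 ± 0.60), LNPEP:123 (6.12, at 56.8 ± 66.2 CPM against 0.810 ± 0.385 CPM, SD) and LNPEP:113 (5.69 ± 0.95) made up the rest of the 10 highest. In all, edgeR called 220 tiles higher and 65 lower of 1563 tested. The groups did not overlap in 630 tiles (40.3%, where chance gives 10%).

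The 5 called PUM2-pool tiles lowest by fitted log2 fold change (-11.8 to -10.3, SE 2.16 to 2.47) had no read in any immunoprecipitate library, so bounds are given. TUBA1B:6 and RBM27:25 were lower by at least 8.13 and 8.11 on the log2 scale, and LNPEP:56, TUBA1B:7 and LNPEP:101 by at least 6.87, 6.69 and 6.58. RBM27:83, also called lower, had 1 immunoprecipitate read against 2333 in Input. Its value of -9.73 ± 1.79 lay below each of these bounds. The calls of the 5 tiles and that of LNPEP:123 were lost whenever 1 Input library of 3 was left out. Without any 1 of these libraries, adjusted p in edgeR was 0.0570 to 0.161 for the 5 tiles and 0.0931 to 0.116 for LNPEP:123. The number called lower moved most: it was 12, 15 and 19 without Input replicate A, B and C, and 115, 113 and 146 without immunoprecipitate replicate A, B and C. By DESeq2, 460 tiles passed (291 higher, 169 lower). Scaling by library size alone moved the median by -0.23 and gave 198 higher and 227 lower tiles. Tests of single barcodes passed 601 higher and 5467 lower. The split of calls into higher and lower thus rests on the scaling and on summing the barcodes of a tile.

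NORAD held the largest share of enriched tiles among the source RNAs: 27 of 66 rose, 1 fell and 38 did not pass, or 29 and 5 when adjusted over the list alone. The 27 tiles lay between tile numbers 9 and 67 in 13 separate runs, the longest of 4 tiles. NORAD:33 was 26.0-fold higher, next to NORAD:34, and NORAD:64 had the lowest value (-2.53 ± 1.47, adjusted p = 0.299 in edgeR). As a set, NORAD tiles stood above the rest of the pool (camera adjusted p = 9.31e-05), the only 1 of 23 source RNAs to do so. With an estimated correlation the adjusted p was 0.605.

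In the mRNAs, enriched tiles were a minority that stood out from a background near 0. LNPEP, an aminopeptidase mRNA, had 32 of 156 tiles higher and 10 lower (35 and 12 adjusted over the list alone), with a median log2 fold change of -0.04. The mRNA of PUM2 itself had 20 of 79 higher and 5 lower (22 and 7 over the list alone), led by PUM2:80 (42.4-fold) and PUM2:48 (16.4-fold). TAOK1 had 20 of 152 higher (TAOK1:88, 21.4-fold) and 4 lower. PRKDC, which encodes a DNA repair kinase, had 12 of 173 higher (PRKDC:139, 4.73-fold) and 5 lower. Its share higher, 6.94%, was below the 14.1% of all tested tiles. The short mRNA of CKS2, a cell cycle gene, had 2 of 7 higher, CKS2:5 by 24.1-fold and CKS2:4 by 14.2-fold. TUBA1B, a tubulin mRNA, went the other way, with 1 tile higher and 4 lower of 20. No mRNA passed the set test (adjusted p of 0.288 or more by camera).

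The 3 highest windows of 5 tiles were LNPEP 110 to 114 (mean log2 fold change 3.57, SD 0.25 over the immunoprecipitate libraries, 4 of 5 called higher), PUM2 47 to 51 (3.43, SD 0.84, 3 called higher) and EIF1AD 33 to 37 (3.42, SD 0.29), where only tiles 36 and 37 were called higher and the others were below 0. The lowest were TUBA1B 6 to 10 (-3.08, SD 0.02), which holds 2 tiles set at their bound, and RBM27 25 to 29 (-1.89, SD 0.25), which holds 1.

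**Figure D1:**
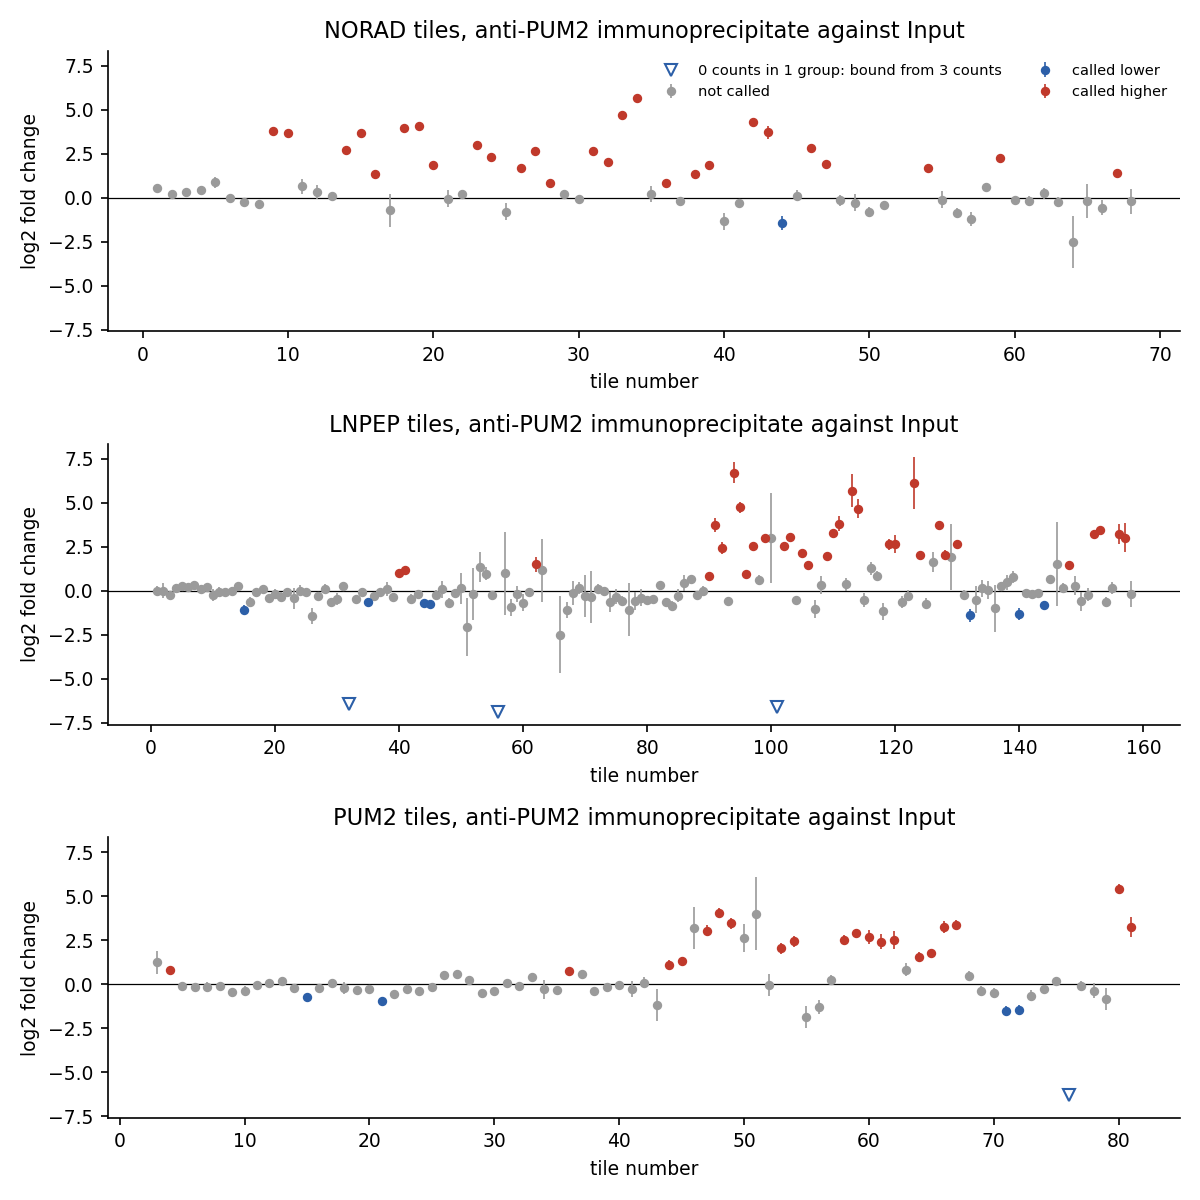
Log2 fold change (immunoprecipitate against Input) by tile number for NORAD, LNPEP and the PUM2 mRNA, with bars for the SE of the edgeR fit (3 libraries per group) and open triangles for tiles with no immunoprecipitate read, set at their bound. Enriched tiles run along NORAD between tiles 9 and 67, and lie mostly at higher tile numbers in LNPEP and PUM2.

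In the MS2 pool, precipitation of tagged MCP through FLAG left a set of tiles at 0.369 to 0.689 of their scaled Input count and raised others slightly, among them the 8 most abundant. The lowest were ms2-4x:88 (log2 fold change -1.44 ± 0.28, SE, n = 3 against 3), ms2-4x:93 (-1.43 ± 0.24), ms2-4x:50 (-1.41 ± 0.28), ms2-4x:71 (-1.39 ± 0.25) and ms2-4x:79 (-1.37 ± 0.27). The highest was ms2-4x:8 (0.77 ± 0.07, 1.70-fold), higher for all 50 of its barcodes, followed, among tiles whose libraries did not overlap, by tiles 7, 4, 10, 5, 89, 3, 6, 57 and 2 at 0.52 to 0.64. edgeR called 22 tiles higher and 33 lower of 104, and all 20 calls of at least 2-fold were lower. Without FLAG replicate 1, 2 and 3 the tiles called higher numbered 32, 13 and 15, and those called lower 41, 30 and 25. The call of ms2-4x:57 was lost without FLAG replicate 2 or 3 (adjusted p up to 0.0632 in edgeR). Scaling by library size alone moved the median by -0.27 and gave 8 higher and 43 lower.

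Precipitation through HA gave 24 tiles higher and 32 lower. The lowest were ms2-4x:93 (-1.45 ± 0.24), ms2-4x:88 (-1.45 ± 0.28), ms2-4x:79 (-1.37 ± 0.27), ms2-4x:90 (-1.34 ± 0.32) and ms2-4x:102 (-1.31 ± 0.48), and the highest again ms2-4x:8 (0.77 ± 0.07). The call of ms2-4x:102 was lost without HA replicate 2 or 3 or Input replicate 2 or 3 (adjusted p up to 0.126 in edgeR). Library size alone moved the median by -0.29 and gave 7 higher and 43 lower. In the HA values no tile lay between -0.76 and -0.43, which parted 31 tiles (median -1.13) from 73 (median 0.23); this gap was sought after the values were seen. In FLAG the medians of the same sets were -1.16 and 0.19, but the sets overlapped: 28 of the 31 tiles lay below all others. Of the 31 tiles, 25 had numbers of 68 or more, where 38 tiles were tested, and 6 had lower numbers, where 66 were tested. The border at 68 was not fixed in advance and no label gives it, so these counts are only a description.

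The antibodies, which recognise different tags on 1 protein, gave matching lists: 51 tiles were called the same way with both, 22 higher and 29 lower, and 0 in opposite directions. Independent lists of these sizes would share 5.08 and 10.2, and unchanged groups simulated with a shared Input shared 0.03 and 0.01. The covariance of the log2 fold changes across tiles was 0.422, against 0.0233 in the simulations (95% range 0.0137 to 0.0337). No tile was changed in the simulations, so few calls could arise there, and their shared counts do not test agreement between the antibodies. The simulations also leave out the deviations that FLAG and HA libraries of the same number share. No control precipitation was among the MS2 groups, so effects common to any precipitation were not told apart from recovery with MCP. Between FLAG and HA directly, edgeR called 0 tiles; 1 had an unadjusted p under 0.05 and DESeq2 called 0. The smallest p values were those of ms2-4x:13, ms2-4x:51 and ms2-4x:83, none of which passed (adjusted p = 1.00 in edgeR).

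**Figure D2:**
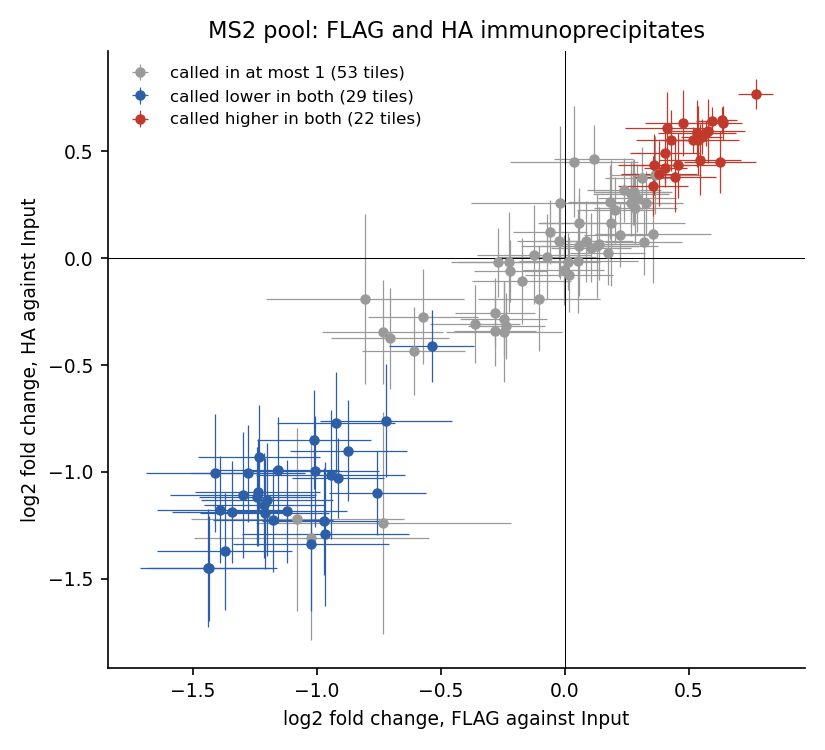
Log2 fold change against Input of the 104 MS2-pool tiles, FLAG on the horizontal and HA on the vertical axis, with bars for the SE of the edgeR fit (3 libraries per group). The 29 tiles called lower and the 22 called higher in both lie along the diagonal.

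Tiles of hTR, the RNA subunit and template of telomerase, differed along the tile numbers in the FLAG-hTERT immunoprecipitate. Tiles 194 to 307 had a median log2 ratio to Input of 1.30, 1.01 and 0.75 in replicates 1, 2 and 3, and tiles 421 to 614 one of -0.40, -1.06 and -0.91. Tiles 1 to 193 had medians of 0.50, 0.04 and 0.24, and tiles 308 to 420 of 1.04, 0.36 and 0.14. The 3 highest windows of 5 tiles, 214 to 218, 237 to 241 and 220 to 224, reached mean log2 fold changes of 1.18 (SD 0.52), 1.14 (SD 0.44) and 1.13 (SD 0.55), and the lowest, 526 to 530 and 481 to 485, were at -1.10 (SD 0.27) and -1.02 (SD 0.07). Without pairing, edgeR called 0 of 614 tiles, 252 had an unadjusted p under 0.05, and DESeq2 called 144 (92 higher, 52 lower). The smallest p values belonged to hTR_373 (1.35 ± 0.30), hTR_378 (1.21 ± 0.27) and hTR_537 (-1.47 ± 0.34), all with an adjusted p of 0.0621 in edgeR. With the replicate number as a block, 343 tiles passed (177 higher, 166 lower), among them 92.1% of tiles 194 to 307 as higher and 81.4% of tiles 421 to 614 as lower. In the unpaired fit, the 0 calls became 67 without replicate 1 of the immunoprecipitate, 275 without Input replicate 1, 403 without both and 290 with library size as the only scaling, and stayed 0 without any other 1 library.

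**Figure D3:**
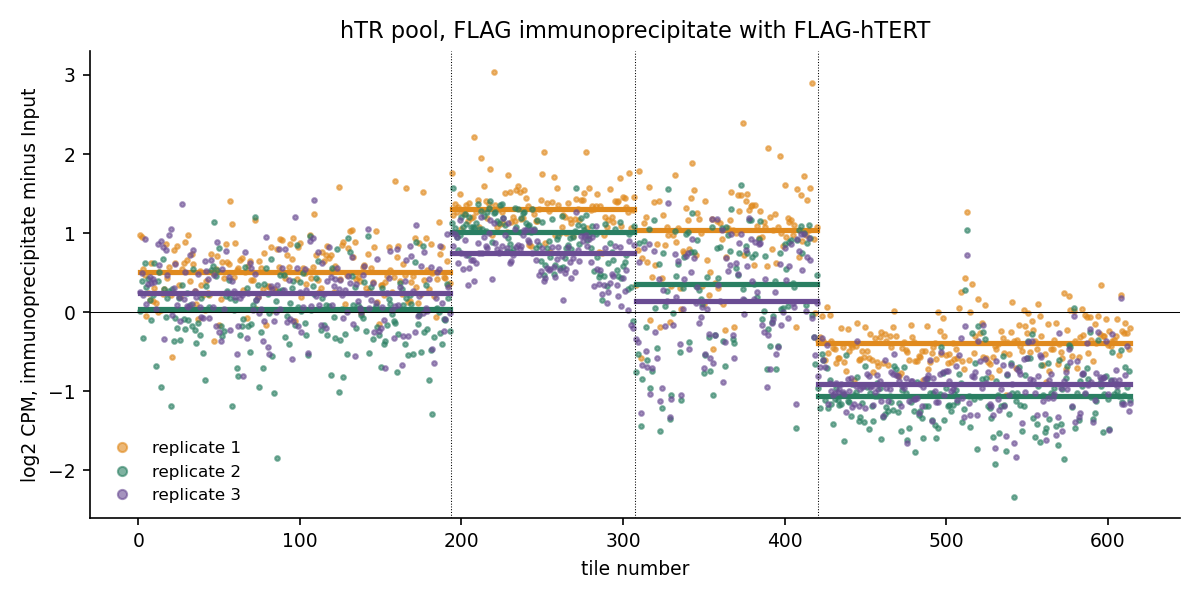
Log2 CPM in the immunoprecipitate minus Input for each hTR tile in each of 3 replicates, by tile number, with thick lines at the median of each of 4 segments. Tiles 194 to 307 lie above and tiles 421 to 614 below 0 in the median of every replicate.

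Tiles enriched in the FLAG-GFP-CTCF immunoprecipitate came from several RNAs. No control precipitation was among the groups, so binding by CTCF was not tested. WRAP53_1 was 2.31-fold higher than in Input (log2 fold change 1.21 ± 0.26, SE, n = 3 against 3), and GAPDH_2, from a glycolytic enzyme mRNA, was 2.29-fold higher (1.20 ± 0.24). XIST, the RNA that coats the inactive X chromosome, gave XIST_106 (1.12 ± 0.17) and the neighbours XIST_57 (1.07 ± 0.18), XIST_58 (1.05 ± 0.20) and XIST_56 (1.05 ± 0.19). TSIX, its antisense RNA, gave TSIX_198 (1.10 ± 0.22) and TSIX_5 (1.09 ± 0.17). It also gave the 5 lowest of the tiles called in the unpaired fit whose libraries did not overlap. These were TSIX_455 (-1.43 ± 0.25), TSIX_117 (-1.20 ± 0.23), TSIX_125 (-1.07 ± 0.19), TSIX_467 (-1.05 ± 0.17) and TSIX_365 (-1.02 ± 0.22). JPX_3 (1.09 ± 0.20), from an X-inactivation RNA, and WRAP53_27 (1.03 ± 0.18) completed the 10 highest of the same called tiles. Some tiles that did not pass lay further out, among them TSIX_415 (1.60), SRA1_15 (1.56) and TSIX_200 (-1.98). edgeR called 28 tiles higher and 19 lower of 977, and 276 had an unadjusted p under 0.05.

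The size of this CTCF list depended on replicate 1 and on pairing. With the replicate number as a block, 270 tiles passed (151 higher, 119 lower), all 47 among them, and DESeq2 passed 174. Among tiles called in the blocked fit, MBP_1 (1.93 ± 0.42) and MBP_2 (1.40 ± 0.22) were highest. Of its 5 lowest calls, 3 were XIST_232 (-1.81 ± 0.54), XIST_31 (-1.36 ± 0.32) and XIST_241 (-1.11 ± 0.19). In the unpaired fit MBP_1 (1.52), MBP_2 (1.32) and XIST_232 (-1.22) also had large values but did not pass. Without Input replicate 1, immunoprecipitate replicate 1 or both, 135, 111 and 452 tiles passed, whereas leaving out replicate 2 or 3 of either fraction gave 0, and none of the named tiles then passed (adjusted p up to 0.243 in edgeR). The highest windows of 5 tiles were SRA1 12 to 16 (mean 0.96, SD 0.24, 0 called), XIST 56 to 60 (0.95, SD 0.10, 4 called higher) and XIST 83 to 87 (0.87, SD 0.15, 1 called higher), and the lowest XIST 157 to 161 (-0.70, SD 0.10) and TSIX 131 to 135 (-0.69, SD 0.06), with 1 called lower in each.

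The source RNAs of the CTCF pool spread over less than 1 unit of log2 fold change. Medians were 0.53 for WRAP53, 0.53 for GAPDH, 0.40 for SRA1, 0.27 for MBP, 0.26 for PPIA, 0.22 for JPX, 0.14 for FIRRE, 0.03 for XIST and -0.17 for TSIX. In the unpaired fit 2 of 28 WRAP53 tiles rose (5 adjusted over the list alone), 1 of 20 GAPDH tiles (3), 1 of 26 SRA1 tiles (3), 4 of 87 MBP tiles (9), 3 of 29 PPIA tiles (3), 2 of 21 JPX tiles (5) and 0 of 52 FIRRE tiles (0), with none lower. In TSIX 6 rose and 16 fell of 471, and in XIST 9 rose and 3 fell of 243, the same counts over each list alone. With the replicate number as a block, 17 WRAP53, 12 GAPDH, 9 SRA1, 20 MBP, 10 PPIA, 8 JPX and 13 FIRRE tiles were higher and 0, 0, 0, 5, 0, 1 and 3 lower, TSIX had 23 higher and 79 lower, and XIST 39 higher and 31 lower. Camera placed 7 RNAs above the rest of the pool and TSIX and the list of RNAs linked to CTCF or X inactivation below it, at a preset correlation (adjusted p of 0.0465 or less), and did not place XIST on either side. With an estimated correlation 1 of these 9 calls held, that of the list (adjusted p = 0.0402), whose 841 tiles include all 471 of TSIX. Of the 8 RNAs listed, 6 have tiles, so the list was set against GAPDH, MBP and PPIA alone. The others had an adjusted p = 0.0670 for TSIX, 0.416 for WRAP53, GAPDH, SRA1 and JPX, 0.328 for MBP and PPIA, and 0.282 for FIRRE. The call of JPX was lost without replicate 1, and that of FIRRE without replicate 1 or 2 (camera adjusted p = 0.127, 0.0894 and 0.0880, in this order).

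**Figure D4:**
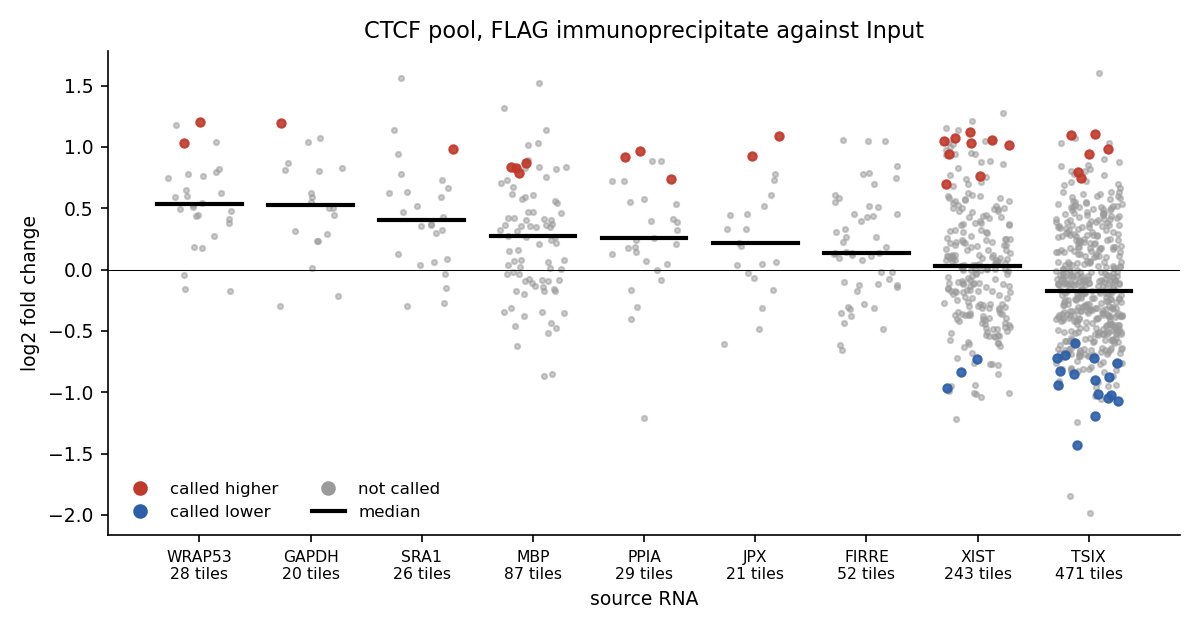
Log2 fold change of each CTCF-pool tile (immunoprecipitate against Input) by source RNA, ordered by median, with coloured points for tiles that edgeR called higher or lower and bars for the medians. Medians run from 0.53 for WRAP53 to -0.17 for TSIX.

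The WRAP53 pool with CTCF showed small differences between tiles and 1 large one. The tile ctrl_1 fell by 1.11 ± 0.17 on the log2 scale (SE, n = 3 against 3), from 305743 ± 53242 CPM in Input to 142015 ± 8951 CPM (SD, after TMM scaling), with 0 of its 35 barcodes higher. The tile wt_1 was at 0.03 ± 0.05. Among called tiles whose libraries did not overlap, the highest were single_16 (0.39 ± 0.06, 1.31-fold), stem_29 (0.27 ± 0.04, 1.21-fold), stem_21 (0.16 ± 0.02), stem_12 (0.15 ± 0.05) and stem_11 (0.13 ± 0.05). Among the same tiles the lowest after ctrl_1 were stem_16 (-0.16 ± 0.05), stem_25 (-0.15 ± 0.05), stem_26 (-0.14 ± 0.04) and single_1 (-0.12 ± 0.05). edgeR called 5 tiles higher and 7 lower of 55, and neither single nor stem tiles stood apart as a class (0 of 2 by camera, adjusted p of 0.800 or more).

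Because ctrl_1 held so many reads, scaling mattered in the WRAP53 pool. By library size alone the median moved by 0.22, 45 tiles were higher and 1 lower, and stem_16, stem_25, stem_26 and single_1 turned positive without passing. With ctrl_1 left out and TMM scaling kept, 5 tiles were higher and 5 lower, and stem_16, stem_25, stem_26 and single_1 were still called lower. The count of calls was 5 without Input replicate 1 (4 higher, 1 lower) and 6 without Input replicate 2 (5 higher, 1 lower). Without immunoprecipitate replicate 3 it was 6 (4 higher, 2 lower), so the tiles called lower were mostly lost in these fits. The calls of single_16, stem_29, stem_21 and ctrl_1 held in every fit that left out 1 library, and those of the other 6 named tiles were each lost in at least 1 of these (adjusted p up to 0.323 in edgeR).

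Measured against wt_1 within each library, 9 of 53 single and stem tiles differed between the FLAG-GFP-CTCF immunoprecipitate and Input. The rises were 0.36 ± 0.07 for single_16, 0.24 ± 0.05 for stem_29 and 0.13 ± 0.02 for stem_21 (SE, n = 3 against 3, adjusted p 6.33e-06, 4.36e-05 and 4.49e-08 in limma). The 5 largest falls were stem_16 (-0.19 ± 0.06), stem_25 (-0.18 ± 0.06), stem_26 (-0.17 ± 0.05), stem_22 (-0.16 ± 0.05) and single_1 (-0.15 ± 0.05). The 53 differences share wt_1 and so are not independent. Of the 9 calls, 2 were made without replicate 1 and 3 without replicate 3. The calls of single_16 and stem_21 held in every fit that left out 1 replicate. That of stem_29 missed the threshold without replicate 1 (adjusted p = 0.0519 in limma). Each of the 6 falls was lost in at least 2 of the 3 fits, and stem_25 and the fall not named above were lost in all 3.

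**Figure D5:**
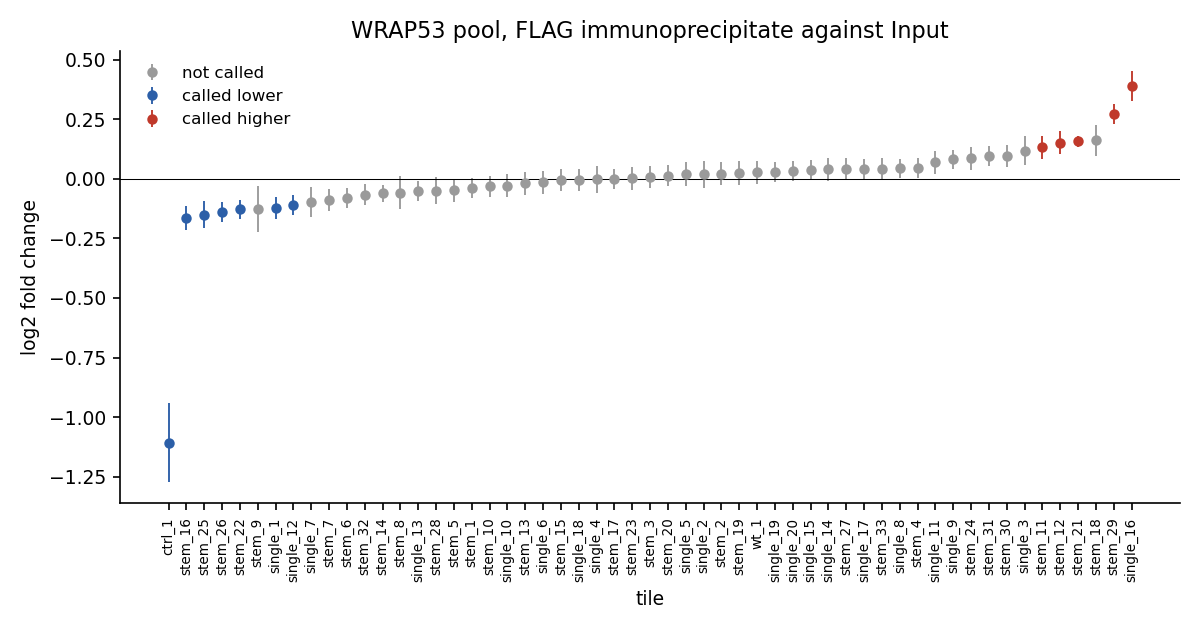
Log2 fold change (immunoprecipitate against Input) of the 55 WRAP53-pool tiles in rising order, with bars for the SE of the edgeR fit (3 libraries per group). The tile ctrl_1 lies at -1.11 and all others between -0.16 and 0.39.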

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

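The fits without each tile's barcode of most reads, without the 8 tiles of most reads, without ctrl_1 without both fractions of replicate 1 and with the PUM2 column letter as a block were chosen after the data were seen. RLE size factors and the count filters left each count within 1.5 times its value, as did the block in the MS2 pool. Leaving out 1 library gave 192 to 410 calls for PUM2, 40 to 73 for FLAG, 42 to 51 for HA, 0 for FLAG against HA, 0 to 275 for hTR, 0 to 135 for CTCF and 5 to 11 for the WRAP53 pool. Leaving out 1 replicate gave 7 to 9 CTCF classes, 0 WRAP53-pool classes and 2 to 10 altered tiles, and PUM2 kept 1 class without any 1 library. DESeq2 gave 460 PUM2 tiles, 144 hTR tiles and 174 CTCF tiles. Library size alone gave 290 hTR tiles and 46 WRAP53-pool tiles. The block gave 343 hTR tiles, 270 CTCF tiles and 4 WRAP53-pool tiles (3 higher, 1 lower). Same-numbered WRAP53-pool libraries correlated at 0.23, 0.25 and 0.02. Its numbers were not counted as pairing, though only replicate 3 fell short of the bound of 0.1. PUM2 libraries that share a column letter did not pair either (correlations of -0.04, 0.01 and -0.02). The letter as a block gave 294 PUM2 tiles (215 higher, 79 lower, 255 shared) and 1 class. It did not call LNPEP:123 or the 5 tiles lowest by fitted value. A log2 fold change of at least 1 left 20 FLAG, 24 HA, 16 shared, 18 CTCF and 1 WRAP53-pool tiles, by its own construction. Tests per barcode passed 6068 of 30210 in the PUM2 pool (601 higher, 5467 lower). This turned the balance of the PUM2 calls over: 9.90% were higher, against 77.2% of calls by tile. Per barcode, 26 passed for FLAG (25 higher, 1 lower), 19 for HA (18 higher, 1 lower) and 0 for CTCF. In the WRAP53 pool 37 passed, of which 35 were ctrl_1. An estimated correlation left 0 PUM2 and 1 CTCF class. Without both fractions of replicate 1, 403 hTR and 452 CTCF tiles passed. Under library size alone stem_16, stem_25, stem_26 and single_1 reversed, to 0.0591, 0.0743, 0.0818 and 0.0976, since the scaling moves all tiles of that pool by 0.22. Except where the construction shows it, the cause was not tested. Over named tiles and classes, 2148 of 2474 values under an alternative kept direction and side of the threshold, 191 lost and 116 gained the threshold, 15 uncalled values changed sign and 4 called ones reversed. Not run were scaling to negative controls, a PUM2 block by the number in the labels and shared CTCF and WRAP53 tiles.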

Other observations

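The tests of barcodes, of hTR replicates, of tile position and of neighbouring tiles were chosen after the results they bear on were seen. In the mRNAs of the PUM2 pool, enriched tiles gathered at high tile numbers: 152 of the 193 called higher in 22 mRNAs (78.8%) lay in the upper part of the numbering, beyond its midpoint, which holds 50.1% of the tested tiles. Most did so in 17 of the 22 mRNAs, among them all 9 of RBM27, all 6 of SDAD1 and 29 of 32 of LNPEP, but not in BUB3 (5 of 11), VAPA (4 of 8), NR3C1 (4 of 8), IER5 (3 of 6) and HNRNPA2B1 (0 of 4). Shifting the calls around each mRNA gave such a share in none of 100000 resamples (permutation test, one-sided, p = 1e-05, the smallest they can give). If tile numbers run towards the 3' end, which names do not state, the 78.8% would be consistent with recovery from 3' untranslated regions, where Pumilio proteins are known to bind.

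Neighbouring tile numbers moved together. Across 1522 neighbours in the PUM2 pool the Spearman correlation of log2 fold change was 0.302 (highest of 100000 permutations within source RNAs, 0.134), and across 963 in the CTCF pool 0.410 (highest 0.278); both had p = 1e-05 in a one-sided permutation test, the smallest it can give. Tiles are not independent replicates, and overlap of neighbouring tiles in sequence may account for the values of 0.302 and 0.410, though the overlap itself was not used here.

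For the enriched PUM2 tiles, reliance on 1 barcode was argued against: without each tile's barcode of most immunoprecipitate reads, 215 of the 220 (97.7%) were called higher again. The median tile had 86.4% of its barcodes higher, which argues against a few barcodes for the set, though not for each tile: VAPA:18 had 8 of 18 higher. Scarcity in Input as the whole cause was argued against too, since 62 of the 220 (28.2%, Wilson 95% interval 22.7% to 34.5%) exceeded the median Input CPM of tested tiles. The other tiles were below that median, and scarcity stays open for them. Binding by PUM2, the precipitated protein, stays open and was not tested against a control precipitation.

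For the MS2 tiles, Input abundance stays open as a cause of the depleted set. Across all 104 tested tiles the FLAG log2 fold change had a Spearman correlation of 0.406 with Input log2 CPM (0.385 for HA). Across tiles from number 10 on it was 0.253 (95% interval 0.0557 to 0.432), and 0.230 for HA. The rule set in advance counted a FLAG value under 0.3 against abundance, and 0.253 met it. The interval, which that rule did not ask for, reaches past 0.3, though not to the higher bound set for a cause. Abundance is left open on the ground of that interval. A few barcodes did not carry the set, since the median tile called lower had 12% of its barcodes higher. Differences of hairpin sequence or structure between tiles were not tested.

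For the hTR tiles, replicate 1 alone does not account for the difference between tiles 194 to 307 and tiles 421 to 614: with borders set in replicate 1, it was 2.08 in replicate 2 and 1.66 in replicate 3 (log2). Matching tiles of both segments by Input CPM left a median difference of 1.64, which argues against Input abundance. Tiles 1 to 193 were scarcer in Input than the rest (median log2 CPM of 8.12 against 9.75 for tiles 194 to 307 in replicate 1, and 7.27 against 11.1 in replicate 2), and a difference between parts of the oligonucleotide pool stays open as a cause of the segments beside binding by hTERT.

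With 10 splits of 6 libraries into 3 and 3, the share of splits is never under 0.1, too few for a share under 0.05. The real split and the highest other gave 285 and 0 PUM2 calls, 55 and 0 for FLAG, 56 and 0 for HA, 0 and 10 for FLAG against HA, 0 and 0 for hTR, 47 and 0 for CTCF, 12 and 0 for the WRAP53 pool and 9 and 0 for altered tiles. For classes these were 1 and 1 in the PUM2 pool, 9 and 9 in the CTCF pool and 0 and 0 in the WRAP53 pool. Splits with as many calls as the real one, itself included, numbered 4 for PUM2 classes, 3 for CTCF classes, 10 for FLAG against HA, hTR and WRAP53-pool classes, and 1 elsewhere. The same 9 CTCF classes passed in 2 splits that mix the fractions. Every mixed split puts 2 libraries of 1 fraction with 1 of the other, so part of the difference between the fractions remains. The direction of the classes in these splits was not kept. The splits therefore do not show whether the CTCF classes are tied to the immunoprecipitate, and the same holds for PUM2 classes. The cause was not tested. With the replicate block, the 3 other splits that part the same 3 pairs gave 0 hTR and 0 CTCF calls, against 343 and 270. These splits are also too few for a share under 0.05. Each puts the difference between the fractions into the spread, so their 0 calls say nothing of its cause.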
